A study of Homo sapiens with 39 samples.

How the data were processed

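The series measured RNA of 2 lung cancer cell lines on 39 Illumina bead arrays. The deposited values were probe intensity on a linear scale. The labels record RNA extraction with a column kit and amplification to biotin-labelled cRNA, but no scanner, summary or normalization software. The normalization by the authors is not recorded in the sources used here. The values showed quartiles that differed between arrays by at most 0.0719 on the log2 scale and sorted values that were not identical, and they ran from 60.0 to 21062 with no values near 0, so background had not been subtracted to 0 and folds of dim probes are understated. Detection calls and genome positions were not used here, and genes are given by symbol. As the labels' time field and title disagreed for 1 H209 vehicle array (replicate 3, title 24 h, field 8 h) and the field was absent for another (replicate 2, 24 h), the title was used for every array.

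Of 48107 probes, 20 with empty cells (47 cells) were left out. Values below the percentile 1 of the positive values (intensity 75.8) were set to it, and log2 intensity was taken. Probes above the table's median (log2 6.55, intensity 93.6) in at least 2 arrays were kept, 42925 in all. Of these, 26943 had exactly 1 gene symbol; the rest were left out of the gene tests. A gene with several kept probes (5878 genes) was represented by the probe with the highest mean, giving 18555 genes. The deposited normalization was kept because quartiles lay within 0.1.

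Each gene was fitted with limma 3.58.1 in R 4.3.3 as 14 group means (line, treatment and time) over all 39 arrays, with 25 residual degrees of freedom per gene and 6.79 prior degrees of freedom from the empirical Bayes step. Contrasts gave DKFZ-608 minus time-matched vehicle in each line at 4, 8 and 24 h and for the mean of the 3 times, the difference of that effect between lines (H838 minus H209) and between 24 and 4 h, H838 minus H209 at 0 h, and vehicle at 24 h minus 0 h, 17 contrasts in all. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. The errors given are the standard errors of the moderated fit.

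Counts and lists rested on 26 gene lists: NRF2 targets, thioredoxin and glutathione enzymes, selenoproteins, heat shock response, metallothioneins and zinc response, ATF4 integrated stress response, endoplasmic reticulum unfolded protein response, p53 targets, apoptosis regulators, mitosis and G2/M, DNA replication and S phase, cholesterol biosynthesis, immediate early genes, NF-kB and inflammatory response, interferon response, hypoxia and glycolysis, proteasome subunits, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis and MYC targets, replication-dependent histones, autophagy and lysosome, iron handling and ferroptosis, neuroendocrine lineage, epithelial and mesenchymal lineage, and markers of other cell types. Lists were tested with camera (limma) at an inter-gene correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. Some genes stand in more than 1 list, such as HMOX1, ATF3 and CHAC1. The grouping, the contrasts, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined.

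For each treatment effect the rule named TXNRD1, TXN, HMOX1, NQO1, SRXN1, SLC7A11 and GCLM always; then the 10 largest rises and the 10 largest falls past the test in which every treated array lay on the same side of every time-matched vehicle array; and up to 4 members of each list past the test. For the mean of times the condition on arrays was dropped. For differences of effects and vehicle drift it named the 5 largest in each direction and up to 4 per list, and for the lines at 0 h the 10 largest in each direction, the 7 fixed genes, and up to 4 per list of 4 lists. The text names a subset in that order. The same rule was applied to the fits without 4 arrays and within H838.

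Replicate numbers were checked as pairs by correlating, over genes, the deviations of same-number treated and vehicle arrays from their group means. At 4 h in H209 the 3 pairs had r of 0.48, 0.14 and 0.55, all over 0.1, so the number was taken to pair arrays there. The main fit had no block and leaves this pairing out. Over the 16 pairs r ran from -0.59 to 0.55, with 8 over 0.1, and the block is given as an alternative at every time. In H209 at 8 and 24 h r cannot judge the pairing. There arrays with the other group's profile, described below, push the deviations of same-number arrays apart. The block was fitted over all times of a line at once, so its results at 4 h also rest on the other times.

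The procedure was tested on simulated data with independent noise at each gene's own spread. Changes were given to 200 genes picked at random, and a further list of genes was raised 1.5-fold. Genes that respond in H209 have a spread widened by 4 arrays with the other group's profile, described below. The shares recovered do not hold for such genes: GCLM, at 1.03 ± 0.43 at 4 h in H209, did not pass. At 4 h in H209 the procedure recovered 94% of 1.5-fold, 97% of 2-fold and 100% of 4-fold changes. At 24 h in H838, with 2 against 3 arrays, it recovered 88.1%, 100% and 100%, with 9 false calls in each. Without the 4 arrays, at 8 h in H209 with 1 against 1, it recovered 55.2%, 97% and 98.5%.

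The alternatives set beforehand were quantile normalization, median-centred arrays, no filter, a filter at the percentile 75, log2 of the value plus 16, the mean of a gene's probes, the arrays of the same line or of the contrast alone, the replicate block as a fixed or a random effect, empirical Bayes with trend and robust settings, array weights, a 1.5-fold minimum, the array with conflicting labels left out or placed at 8 h, and each array left out in turn. A fit without 4 H209 arrays (vehicle and DKFZ-608 at 8 h, replicate 2, and vehicle and DKFZ-608 at 24 h, replicate 3), with 21 residual degrees of freedom, and a replicate block with exchanged numbers at 8 h in H209 were added after the data were seen; no array was moved to another group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.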

Results

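RNA was profiled on bead arrays in 2 human lung cancer lines, NCI-H209 (H209), a small cell carcinoma line of neuroendocrine type, and NCI-H838 (H838), an adenocarcinoma line. The KEAP1 gene of H838, a brake on the antioxidant transcription factor NRF2, is known as background to be mutated. Cultures received 100 nM DKFZ-608, a code-named compound that the labels describe as a non-covalent inhibitor of thioredoxin reductase 1 (TXNRD1), in 6.9 µM cyclodextrin, or cyclodextrin alone as vehicle. The 39 arrays comprised 19 of H209 and 20 of H838, with 16 treated and 17 vehicle arrays at 4, 8 or 24 h and 6 vehicle arrays at 0 h. Groups held 3 arrays, except that H209 DKFZ-608 at 8 h, H209 vehicle at 8 h and H838 DKFZ-608 at 24 h held 2. The study's own description counts 40 arrays. Array medians ran from 92.6 to 94.2 intensity units, and the number of arrays limits the precision. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these arrays.

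The comparison at 4 h in H209 asks which transcripts respond early to the inhibitor. Genes of metal binding, protein folding and the stress response were higher in the treated than in the time-matched vehicle arrays (n = 3 against 3). MT1M, a metallothionein that binds zinc and other metals, rose 32.8-fold, from a mean log2 intensity of 6.55 to 11.59 (log2 fold change 5.03 ± 1.06 SE, adjusted p = 0.0126). Its vehicle mean lay at the filter value for dim probes, so the fold is approximate. HMOX1, which degrades haem and is induced by oxidative stress, rose 13.5-fold (3.76 ± 0.85, adjusted p = 0.0239), and HSPA1A, an inducible HSP70 chaperone, rose 7.98-fold (3.00 ± 0.63, adjusted p = 0.012). ATF3, a stress-induced transcription factor, rose 5.03-fold (2.33 ± 0.36, adjusted p = 0.000292). The falls were smaller. CTDSP1, a small phosphatase that acts on RNA polymerase II, fell by 0.81 ± 0.12 on the log2 scale (adjusted p = 0.000292). LFNG, a glycosyltransferase that modifies Notch, fell by 0.77 ± 0.16, and ISL1, a homeobox factor of neuroendocrine cells, fell by 0.66 ± 0.13. limma called 121 of 18555 genes, 98 up and 23 down. In every gene named in this paragraph each treated array lay on the same side of each vehicle array. Chance gives this in 10% of splits of 3 against 3. The naming rule required it of the largest rises and falls, so it adds no evidence. With the replicate number as a block over all times, 129 genes rose and 63 fell. The check of the numbers allows this pairing at 4 h. For the H209 pairs at 8 and 24 h r was negative, but there it cannot judge the pairing. The arrays with the other group's profile, described below, push the deviations of same-number arrays apart. Without vehicle replicate 1, vehicle replicate 2, DKFZ-608 replicate 2 or DKFZ-608 replicate 3 the count was 62, 61, 55 and 66. With the spread estimated from the H209 arrays alone it was 27. That spread, like the errors above, includes 4 H209 arrays at 8 and 24 h with the other group's profile, described below. At 4 h MT1M had an SD of 0.13 in vehicle and 0.16 in treated arrays. From the 4 h arrays of H209 alone 143 genes passed.

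Of the 11 measured genes of metallothioneins and the zinc response, 8 rose at 4 h, and 8 passed when adjusted over the list alone. The median log2 fold change was 3.00 (camera adjusted p = 2.44e-19). MT1H rose 16.1-fold, MT2A 11.8-fold and MT1X 10.5-fold. These sequences are close enough to cross-hybridise, so the members are not fully independent. Of the 24 heat shock genes 6 rose, 18 when adjusted over the list alone (median 0.67, adjusted p = 6.22e-30). Among them were HSPA1B (2.81 ± 0.59), the co-chaperone DNAJB1 (2.54 ± 0.59) and HSPH1 (1.87 ± 0.39). Of the 31 genes of the ATF4 integrated stress response 10 rose, 17 when adjusted over the list alone (median 0.41, adjusted p = 9.97e-32). They included STC2, a secreted glycoprotein (1.39 ± 0.23), DDIT3, which encodes the stress factor CHOP (1.35 ± 0.23), and DDIT4, an inhibitor of mTORC1 (1.27 ± 0.19). Of the 28 immediate early genes 8 rose, 12 when adjusted over the list alone (median 0.24, adjusted p = 2.78e-19). FOS was at 1.91 ± 0.41, the phosphatase gene DUSP1 at 1.77 ± 0.31 and EGR1 at 1.62 ± 0.18. These 4 calls held with an estimated correlation, and no other call at this time did. With the spread from the H209 arrays alone all 4 were lost (adjusted p = 0.206 for each with an estimated correlation).

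Of the 36 measured NRF2 targets HMOX1 alone rose, also when adjusted over the list alone. The median was 0.14, and the list call (adjusted p = 4.82e-06) was lost (adjusted p = 0.518 with an estimated correlation). TXNRD1 itself (0.68 ± 0.29, adjusted p = 0.51), its substrate TXN (0.01 ± 0.11) and NQO1 (0.19 ± 0.15) did not pass. Nor did SRXN1 (0.55 ± 0.56), the cystine transporter gene SLC7A11 (0.34 ± 0.20) or GCLM, a subunit of the enzyme that limits glutathione synthesis (1.03 ± 0.43). These errors include the spread of the 4 H209 arrays with the other group's profile, so the genes are not shown to be unchanged. Iron handling (2 of 16 up and 2 when adjusted over the list alone, HMOX1 and CHAC1, which degrades glutathione; median 0.05, adjusted p = 0.0317) was lost (adjusted p = 0.155 with an estimated correlation). Hypoxia and glycolysis (1 of 30 up, the angiogenic factor VEGFA, and 2 when adjusted over the list alone; median 0.01, adjusted p = 0.0391) was lost as well (adjusted p = 0.616 with an estimated correlation). Lower values were called by camera for mitosis and G2/M (30 genes, median -0.11, adjusted p = 0.0317), oxidative phosphorylation (34 genes, median -0.08, adjusted p = 0.00103) and ribosomal proteins (35 genes, median -0.06, adjusted p = 0.0317). No member passed the test, also when adjusted over the list alone. Those calls were lost (adjusted p = 0.717, adjusted p = 0.299 and adjusted p = 0.275 with an estimated correlation).

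The remaining lists were not called at 4 h. XBP1, a factor of the unfolded protein response, rose (0.58 ± 0.13) as 1 of 21 genes of the endoplasmic reticulum response, of which 1 was up and 1 down when adjusted over the list alone. Of 24 apoptosis regulators the pro-apoptotic PMAIP1 (1.33 ± 0.20) and the anti-apoptotic MCL1 (0.83 ± 0.13) rose, with 2 up and 2 down when adjusted over the list alone. ISL1 was the 1 of 21 neuroendocrine genes that fell, also when adjusted over the list alone. No member passed, either way, among 34 thioredoxin and glutathione enzymes, 20 selenoproteins, 23 p53 targets, 29 genes of DNA replication and S phase, 20 of cholesterol synthesis, or 20 of the NF-kB response. The same held for 22 of the interferon response, 27 proteasome subunits, 28 genes of ribosome biogenesis and MYC, 16 histones, 26 genes of autophagy and lysosome, 27 epithelial and mesenchymal genes and 12 markers of fibroblasts, leukocytes and endothelium. The median was negative and the camera direction up for thioredoxin and glutathione enzymes, selenoproteins, p53 targets and the markers of other cell types. For neuroendocrine genes the median and the mean were positive and the camera direction was down, and for epithelial genes the mean alone was negative.

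**Figure D1:**
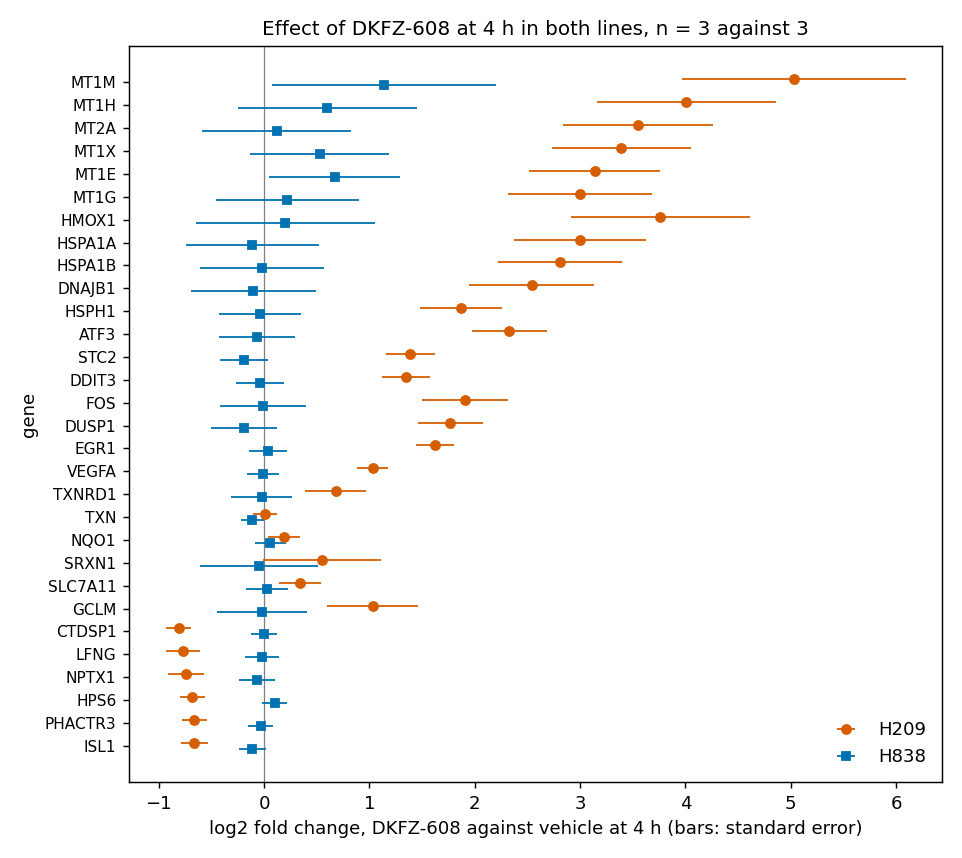
Log2 fold change of DKFZ-608 against vehicle at 4 h (x axis) for 30 genes (y axis) in H209 and H838. Points give the limma estimate from n = 3 against 3 arrays. Bars give its standard error from the fit over all arrays of both lines and all times. They include the spread of the 4 H209 arrays with the other group's profile, so they do not show the spread at 4 h alone. For MT1M the bar was 1.06 in each line, whereas SDs at 4 h were 0.13 (vehicle) and 0.16 (treated) in H209. In H838 these SDs were 0.15 and 0.34. MT1M stood at 5.03 in H209 and 1.14 in H838, and HMOX1 at 3.76 and 0.20.

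The comparisons at 8 and 24 h in H209 ask how the response develops, and there 4 arrays had the profile of the group opposite to their label. The array labelled H209 vehicle 8 h replicate 2 had MT1M at log2 12.17 and HMOX1 at 12.47, against 6.57 and 8.21 in vehicle replicate 1. The array labelled DKFZ-608 8 h replicate 2 had 6.56 and 8.09 against 12.10 and 12.68 in DKFZ-608 replicate 1. At 24 h the array labelled vehicle replicate 3, whose time field says 8 h although its title says 24 h, had MT1M at 10.65 and HMOX1 at 11.01, and the array labelled DKFZ-608 replicate 3 had 6.33 and 7.47. With all arrays as labelled, limma called 0 genes at 8 h (n = 2 against 2), 0 at 24 h (n = 3 against 3) and 0 for the mean of the 3 times. At these, 396, 439 and 796 genes had an unadjusted p under 0.05. Without any effect a share of 0.05 of the 18555 genes would do so, which is more than each of these counts. The same holds for the other unadjusted counts given below, except the 996 for the line difference at 4 h. These counts are thus no sign of further genes that respond. As labelled, HMOX1 was 0.04 ± 1.04 at 8 h and 0.79 ± 0.85 at 24 h, and TXNRD1 0.11 ± 0.35 and 0.49 ± 0.29. For the mean of times the NRF2 list had a median of 0.15, with no member past the test, also when adjusted over the list alone (adjusted p = 6.01e-12, and adjusted p = 0.227 with an estimated correlation). Of the other lists called for the mean of times, that of the ATF4 integrated stress response (median 0.20, adjusted p = 5.15e-26; 14 of 31 up when adjusted over the list alone) held, at adjusted p = 0.0488 with an estimated correlation. With the spread from the H209 arrays alone it was lost (adjusted p = 0.313 with an estimated correlation), and 7 of 31 were up when adjusted over the list alone. The count for the mean of times was 43 without vehicle 8 h replicate 2, 51 without DKFZ-608 8 h replicate 2, 28 without vehicle 24 h replicate 3 and 9 without DKFZ-608 24 h replicate 3. At 8 h 1 gene passed without vehicle replicate 1 and 1 without DKFZ-608 replicate 2.

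**Figure D2:**
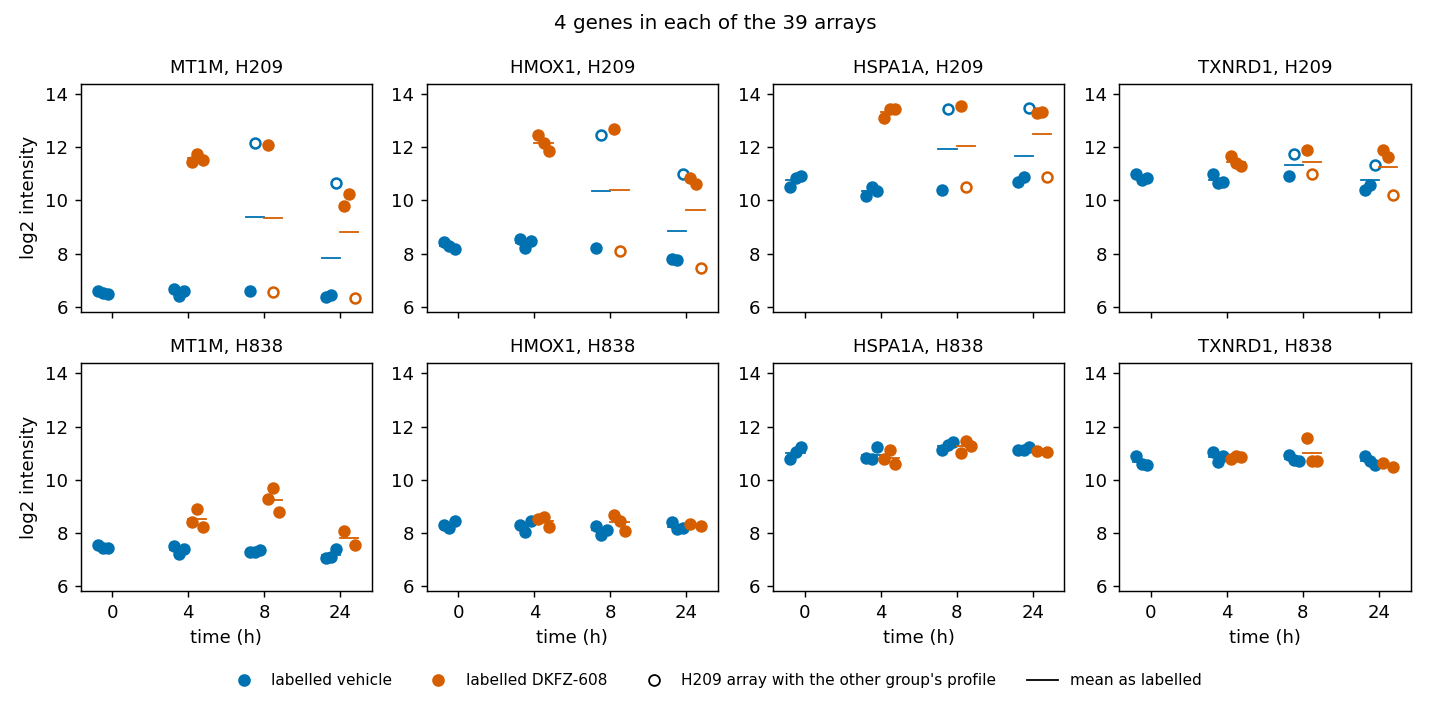
Log2 intensity (y axis) of 4 genes in each of the 39 arrays against time in hours (x axis), by cell line and labelled treatment, with open points for the 4 H209 arrays that had the other group's profile and short lines for group means as labelled. MT1M in the open points lay at 12.17 and 10.65 under vehicle labels and at 6.56 and 6.33 under DKFZ-608 labels.

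A fit without these 4 arrays was added after the data were seen. As the arrays were picked by their expression, its p-values are not independent evidence that treatment changed these genes. In that fit limma called 263 genes at 8 h (189 up and 74 down, n = 1 against 1), 308 at 24 h (226 up and 82 down, n = 2 against 2) and 904 for the mean of times (509 up and 395 down). Each lone array at 8 h was assumed to vary like the other groups. At 24 h HSPA6, a strictly inducible HSP70, rose 54.1-fold (5.76 ± 0.14), MT1M 12.4-fold (3.63 ± 0.20) and HMOX1 7.77-fold (2.96 ± 0.17). Vehicle means of HSPA6 (6.57) and MT1M (6.4) lay near the filter value of 6.55, so their folds are approximate. NRF2 targets rose in number, 27 of 36 at 24 h (29 when adjusted over the list alone, median 0.76, adjusted p = 2.45e-67). They included SRXN1, which reactivates peroxiredoxins (2.79 ± 0.23), the aldo-keto reductase gene AKR1B10 (2.68 ± 0.19) and GCLM (1.55 ± 0.14). TXNRD1 rose 2.44-fold (1.29 ± 0.19), TXN 1.43-fold (0.52 ± 0.10), NQO1 1.83-fold (0.87 ± 0.11) and SLC7A11 1.84-fold (0.88 ± 0.10). Of heat shock genes 13 of 24 rose (21 when adjusted over the list alone, median 0.62), with the co-chaperone BAG3 at 2.94 ± 0.15. Likewise 9 of 11 metallothionein and zinc genes rose (9 when adjusted over the list alone, median 2.67). Of 31 ATF4 genes 9 rose (15 when adjusted over the list alone, median 0.34), with the phosphatase subunit PPP1R15A at 2.00 ± 0.18. FGD3, an exchange factor for CDC42 (-0.91 ± 0.12), NUDT1, which clears oxidised nucleotides (-0.74 ± 0.19), and the transcription factors SOX21 (-0.68 ± 0.12) and FLI1 (-0.67 ± 0.10) fell. A second probe of NUDT1 gave -0.04.

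At 8 h in the same fit HMOX1 rose 22.1-fold (4.47 ± 0.24), MT1M 46.1-fold (5.53 ± 0.28), HSPA6 34.7-fold (5.12 ± 0.20) and GCLM 5.47-fold (2.45 ± 0.19). The lone vehicle array had MT1M at 6.57 and HSPA6 at 6.63, near the filter value, so their folds are approximate. TXNRD1 (0.98 ± 0.27, adjusted p = 0.0606), TXN (-0.11 ± 0.14) and NQO1 (0.33 ± 0.16) did not pass. The lists of NRF2 targets (13 of 36 up, 17 when adjusted over the list alone), heat shock (17 of 24, and 23), metallothioneins and zinc (9 of 11, and 9) and ATF4 (14 of 31, and 19 up and 1 down) were called. Of the genes that rose, 108 were shared by 4 and 8 h, 101 by 8 and 24 h, 84 by 4 and 24 h and 71 by all 3 times. This sharing is in part fixed by the choice of arrays, which were left out by their expression of the genes that changed at 4 h. At 4 h the fit called 226 genes up and 122 down, and all 98 and 23 genes called with every array in the fit were among them. TXNRD1 passed there at 4 h (0.68 ± 0.15, adjusted p = 0.0109), as did 9 of 36 NRF2 targets (13 when adjusted over the list alone, median 0.14, adjusted p = 0.000102 with an estimated correlation). With or without the 4 arrays, probes of a gene differed in size. A second probe of HSPA6 gave 1.08 against 4.45 at 4 h, and a second probe of MT1E gave 2.43 against 3.14.

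**Figure D3:**
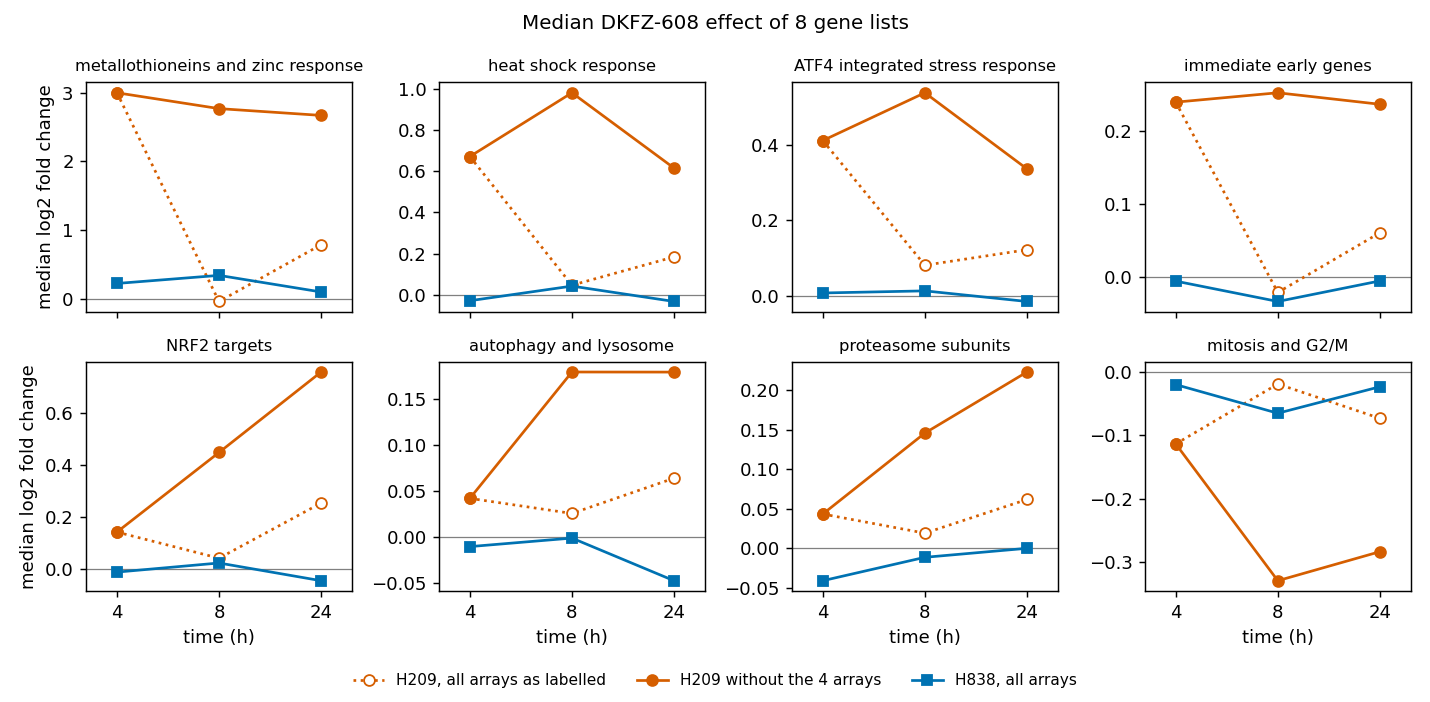
Median log2 fold change of DKFZ-608 against vehicle (y axis, a separate scale in each panel) at 4, 8 and 24 h (x axis) for 8 gene lists, in H209 with all arrays as labelled, in H209 without the 4 arrays and in H838. For NRF2 targets the median in H209 without the 4 arrays was 0.14 at 4 h, 0.45 at 8 h and 0.76 at 24 h.

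The comparisons in H838 ask whether the adenocarcinoma line responds likewise. With all 39 arrays in the fit limma called 0 genes at 4 h (n = 3 against 3), 0 at 8 h (n = 3 against 3), 0 at 24 h (n = 2 against 3) and 0 for the mean of times. At these, 493, 638, 562 and 547 genes had an unadjusted p under 0.05. MT1M was 1.14 ± 1.06 at 4 h, 1.94 ± 1.06 at 8 h and 0.64 ± 1.18 at 24 h, where the errors include the spread of the H209 arrays. With the spread taken from the 20 H838 arrays alone, 3, 5 and 2 genes rose at 4, 8 and 24 h and 4 for the mean of times, each a metallothionein, and none fell. In that fit MT1M rose 2.21-fold at 4 h (1.14 ± 0.18, adjusted p = 0.0159) and 3.84-fold at 8 h (1.94 ± 0.18, adjusted p = 4.38e-06). MT1F rose 1.94-fold at 4 h (0.96 ± 0.15), 2.72-fold at 8 h (1.44 ± 0.15) and 2.06-fold at 24 h (1.04 ± 0.16). In each of these, all treated arrays lay above all vehicle arrays of the same time, which the naming rule required. MT1E (1.10 ± 0.12) and MT1H (1.09 ± 0.11) also rose at 8 h, but a second probe of each gave 0.01 and -0.14. HMOX1 was 0.20 ± 0.14, 0.29 ± 0.14 and 0.06 ± 0.15 at the 3 times, and TXNRD1 -0.02 ± 0.16, 0.21 ± 0.16 and -0.16 ± 0.18. GCLM was -0.02 ± 0.11, 0.06 ± 0.11 and -0.07 ± 0.13, and none of these passed. For the mean of times, with all arrays, camera called the metallothionein and zinc list alone (median 0.24, 0 of 11 past the test and 1 when adjusted over the list alone, adjusted p = 0.00531), which was lost (adjusted p = 0.99 with an estimated correlation). With the spread from the H838 arrays alone 4 of 11 rose for the mean of times, 6 when adjusted over the list alone, and that call held (adjusted p = 0.000564 with an estimated correlation). So did those at 4 h (adjusted p = 0.0104) and 8 h (adjusted p = 0.00142), while that at 24 h was lost (adjusted p = 0.307 with an estimated correlation). The NRF2 list had a median of -0.01 (adjusted p = 0.887; adjusted p = 0.99 with an estimated correlation). The median of the zinc list was 0.22 at 4 h, 0.34 at 8 h and 0.10 at 24 h.

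The difference between the lines was tested as the H838 effect minus the H209 effect. At 4 h, with all arrays, it passed for 9 genes, all with a smaller effect in H838, and 996 genes had an unadjusted p under 0.05. EGR1, an immediate early transcription factor (-1.58 ± 0.25, adjusted p = 0.00385), MXD1, a MYC antagonist (-1.04 ± 0.17), RGS16, a regulator of G protein signalling (-0.98 ± 0.16), CHAC1 (-0.95 ± 0.16) and CCDC117 (-0.79 ± 0.15) differed most. For MT1M the difference was -3.89 (adjusted p = 0.783) and for HMOX1 -3.56 (adjusted p = 0.65), which did not pass. Their errors include the spread of the 4 H209 arrays with the other group's profile, so equal effects are not shown. When adjusted over the list alone the H838 effect was smaller for 13 of 24 heat shock genes, 7 of 11 metallothionein and zinc genes, 14 of 31 ATF4 genes and 10 of 28 immediate early genes. The camera calls of these lists (adjusted p = 2.36e-21, adjusted p = 3.63e-10, adjusted p = 5.38e-21 and adjusted p = 3.38e-12) were lost (adjusted p = 0.107, adjusted p = 0.178, adjusted p = 0.103 and adjusted p = 0.103 with an estimated correlation). limma called 0 genes for the difference at 8 h, 0 at 24 h and 0 for the mean of times, with 475, 467 and 619 at an unadjusted p under 0.05. With the replicate number as a block 27 genes passed at 4 h, 4 of them with a difference above 0. Array weights gave 62, 8 of them above 0, and the arrays of this contrast alone 98, 12 of them above 0. All 4, 8 and 12 genes fell in H209 and had an effect nearer 0 in H838. At 4 h the count was 5 without H209 vehicle replicate 1, 5 without H209 DKFZ-608 replicate 2, 5 without H838 vehicle replicate 1, 5 without H838 DKFZ-608 replicate 1 and 4 without H838 vehicle replicate 3. For the mean of times it was 2 without H209 vehicle 8 h replicate 2.

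Without the 4 arrays the lines differed in 133 genes at 4 h (21 with a difference above 0 and 112 below), 144 at 8 h, 126 at 24 h and 465 for the mean of times (130 and 335). All 21 and all 130 genes with a difference above 0 fell in H209 and had an effect nearer 0 in H838, with medians for the mean of times of -0.35 in H209 and 0.02 in H838. The 112 and 335 rose in H209, and the H838 effect was nearer 0 in 110 and 334. For the mean of times HSPA6 differed by -5.09 ± 0.11, HMOX1 by -3.54 ± 0.14, MT1M by -3.49 ± 0.16 and TXNRD1 by -0.97 ± 0.15. The effect was smaller in H838 for 19 of 36 NRF2 targets (30 when adjusted over the list alone), 22 of 24 heat shock genes (24), 9 of 11 metallothionein and zinc genes (10) and 17 of 31 ATF4 genes (23). The difference was above 0 for LFNG (0.66 ± 0.09), the Wnt and FGF modulator SHISA2 (0.62 ± 0.10) and the lung and foregut transcription factors NKX2-1 (0.61 ± 0.09) and FOXA2 (0.60 ± 0.07). These fell in H209 (LFNG -0.65, SHISA2 -0.59, NKX2-1 -0.57 and FOXA2 -0.54), with H838 effects of 0.00, 0.02, 0.04 and 0.06.

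The change of the effect between 4 and 24 h was tested in each line. In H209, with all arrays, it passed for 6 genes, all with a smaller effect at 24 h, and 846 genes had an unadjusted p under 0.05. Among them were EGR1 (-1.70 ± 0.25, adjusted p = 0.0023), MXD1 (-0.98 ± 0.17), CHAC1 (-0.84 ± 0.16) and CCDC117 (-0.82 ± 0.15). As labelled, the 24 h groups hold a vehicle and a treated array with the other group's profile. This shrinks the effect at 24 h and biases the difference towards a smaller effect there, so the shared direction is not a result. With the spread from the H209 arrays alone no gene passed. The count was 3 without vehicle 4 h replicate 1, 3 without vehicle 24 h replicate 1, 3 without vehicle 24 h replicate 2, 3 without DKFZ-608 4 h replicate 2, 2 without vehicle 4 h replicate 3 and 2 without DKFZ-608 24 h replicate 3. In H838 limma called 0 genes, with 492 at an unadjusted p under 0.05. Without the 4 arrays 73 genes differed in H209, 47 with a difference above 0 and 26 below. The effect at 24 h was farther from 0 than that at 4 h in 45 of the 47 and nearer 0 in 19 of the 26. There the effect on AKR1B10 (2.42 ± 0.25), SRXN1 (2.24 ± 0.30), the vascular factor ANGPT2 (1.89 ± 0.23) and HSPA6 (1.31 ± 0.18) was larger at 24 h, and that on ATF3 (-1.06 ± 0.19) was smaller. Falling vehicle values made part of these differences. From 4 to 24 h vehicle changed by -0.80 for AKR1B10, -0.66 for SRXN1, -0.92 for ANGPT2 and 0.07 for HSPA6, and the treated arrays by 1.62, 1.58, 0.97 and 1.38. Vehicle fell in 40 of the 47 genes (median change -0.25, against 0.68 in treated arrays). Of 36 NRF2 targets 7 had a larger effect at 24 h (24 larger and 1 smaller when adjusted over the list alone; median 0.44, adjusted p = 1.24e-28), a call that held at adjusted p = 5.93e-06 with an estimated correlation. In this list vehicle fell from 4 to 24 h in 34 of 36 genes (median change -0.15, against 0.22 in treated arrays), and in 9 it moved more than the treated arrays did. GCLM changed by -0.49 in vehicle and 0.03 in treated arrays.

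The comparison at 0 h asks how the lines differ before treatment. Neuroendocrine genes were higher in H209 (n = 3 against 3). GRP, the gastrin-releasing peptide of neuroendocrine lung cells, was 161-fold lower in H838 (-7.33 ± 0.07, means 6.33 and 13.66). Its H838 mean lay under the filter value for dim probes (log2 6.55), so the fold is approximate. IGFBP5, which binds insulin-like growth factors (-6.67 ± 0.08), BEX1 (-6.18 ± 0.09), the microtubule regulator STMN3 (-6.03 ± 0.09), the sodium channel subunit SCNN1A (-5.98 ± 0.09) and the granin SCG2 (-5.86 ± 0.12) were also lower. GAGE4, a cancer testis antigen, was 132-fold higher (7.05 ± 0.08). Other GAGE copies and CT45A3 (6.43 ± 0.13) were higher too, although near-identical copies may share probes. limma called 8494 of 18555 genes, 3945 higher and 4549 lower in H838. Of the 21 neuroendocrine genes 19 were lower, 19 when adjusted over the list alone (median -3.13, adjusted p = 2.33e-18). Of the 27 epithelial and mesenchymal genes 19 were higher and 6 lower, 20 and 6 when adjusted over the list alone (median 2.32, adjusted p = 2.04e-08). VIM, vimentin (4.76 ± 0.09), and ANXA1 (4.88 ± 0.15) were higher, while the epithelial EPCAM (-5.11 ± 0.12) and KRT19 (-4.70 ± 0.15) were lower in H838. Cholesterol synthesis was lower in 15 of 20 genes and higher in 1, with the same counts when adjusted over the list alone (median -0.79, adjusted p = 4.27e-05). These 3 calls held with an estimated correlation; no other call at 0 h did.

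Among NRF2 targets at 0 h, 16 of 36 were higher and 6 lower in H838, with the same counts when adjusted over the list alone, and the list was not called (median 0.16, adjusted p = 0.362). SRXN1 (2.70 ± 0.56), BLVRB, a biliverdin reductase (2.23 ± 0.31), GCLM (2.14 ± 0.43), NQO1 (1.13 ± 0.15) and TXN (0.34 ± 0.11) were higher. AKR1C2 (-5.63 ± 0.29) and the glutathione peroxidase GPX2 (-5.25 ± 0.14) were lower, while TXNRD1 (-0.19 ± 0.29), HMOX1 (0.03 ± 0.85) and SLC7A11 (-0.19 ± 0.20) did not pass. Of 34 thioredoxin and glutathione enzymes 16 were higher and 8 lower, with the same counts when adjusted over the list alone (median 0.27, adjusted p = 0.0915). MGST1, a membrane glutathione transferase (32-fold), and the mitochondrial superoxide dismutase SOD2 (3.03 ± 0.11) were higher and TXNIP, which binds thioredoxin (-3.97 ± 0.11), was lower.

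The vehicle arrays at 24 and 0 h show how far untreated cultures drifted. In H838 mitotic genes rose, 26 of 30 members of the mitosis and G2/M list, 27 when adjusted over the list alone (median 0.84, adjusted p = 1.47e-54, and adjusted p = 0.00705 with an estimated correlation). The spindle protein DLGAP5 rose by 1.48 ± 0.18, cyclin B1 (CCNB1) by 1.42 ± 0.23 and the spindle-binding PSRC1 by 1.33 ± 0.19 (n = 3 against 3). Against 0 h the list median was 0.41 at 4 h, 0.81 at 8 h and 0.84 at 24 h. The ubiquitin ligase MARCHF4 (-1.20 ± 0.20), the histone H2AC18 (-1.10 ± 0.17) and CCN1, a matrix protein (-0.98 ± 0.19), fell. Of 29 genes of DNA replication and S phase 5 fell, with 1 up and 10 down when adjusted over the list alone (median -0.17, adjusted p = 5.02e-06). Of 16 histones 6 fell, with 1 up and 6 down when adjusted over the list alone (median -0.08, adjusted p = 0.00233). Both calls were lost (adjusted p = 0.309 and adjusted p = 0.105 with an estimated correlation). limma called 351 genes, 197 up and 154 down, and after quantile normalization 169 up and 196 down. The count was 103 without vehicle 0 h replicate 1, 179 without vehicle 0 h replicate 2, 167 without vehicle 24 h replicate 2 and 202 without vehicle 24 h replicate 3. With the replicate number as a fixed block it was 636.

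In H209 the vehicle arrays at 24 and 0 h differed in 3 genes, all lower at 24 h (n = 3 against 3), with 697 genes at an unadjusted p under 0.05. They were the smooth muscle actins ACTA2 (-2.17 ± 0.20, adjusted p = 4.15e-08) and ACTG2 (-2.10 ± 0.14, adjusted p = 1.19e-11) and S100A10 (-0.80 ± 0.14, adjusted p = 0.0201). With vehicle replicate 2 at 8 h and vehicle replicate 3 at 24 h left aside, ACTA2 was -0.56 at 4 h, -1.47 at 8 h and -2.44 at 24 h against 0 h, in 3, 1 and 2 arrays. Without the 4 arrays 1 gene was higher and 10 were lower.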

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

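All explanations weighed in this part, and the tests of them, including the splits of the arrays, were chosen after the values had been seen.

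In H209, 4 arrays had the expression profile of the group opposite to their label. A score over the 143 genes called at 4 h from the 4 h arrays of H209 alone ran from -0.03 to 0.06 in the other vehicle arrays and from 0.72 to 1.04 in the other treated arrays. It was 0.99 in vehicle 8 h replicate 2 and 0.87 in vehicle 24 h replicate 3, but 0.05 in DKFZ-608 8 h replicate 2 and -0.04 in DKFZ-608 24 h replicate 3. Exchanged labels of same-number arrays may explain this but stay untested, since the pair was singled out by its expression: that the split of the 24 h arrays exchanging the replicate 3 pair called 459 genes, and the highest other split 1, restates the pattern. Treated cultures that did not respond would leave the vehicle arrays unchanged, whereas 2 arrays labelled vehicle lay over the midpoint of the score, and mixed treated and vehicle RNA would give shares between 0 and 1, whereas the lowest share of the resembled group was 1; neither accounts for the pattern, the exchange stays open, and no array was relabelled.

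Few genes changed in H838, although H209 responded at 4 h. A high starting level in H838 could limit a further rise, but in the 61 of 98 genes that start no higher there the median H838 effect was 0.027 (quartiles -0.04 and 0.071), against 0.668 in H209. Exchanged labels of H838 arrays could hide an effect, but metallothionein level parted DKFZ-608 from vehicle arrays at 3 of 3 times, with the lowest treated and highest vehicle array at 9.11 and 8.84 at 4 h, 9.42 and 8.82 at 8 h and 8.84 and 8.72 at 24 h. Too wide a spread in H838 could do the same, but for 97 of the 98 genes the upper limit in H838 lay under the H209 effect. That comparison takes the H209 effects, picked because they passed, as fixed. Tested directly with all arrays, the line difference at 4 h passed for 9 genes. Exchanged labels do not account for the pattern, nor does a high starting level for the 61 genes. Genes that start higher in H838 were not tested, and the comparison of limits does not settle the spread. A difference in biology between the lines, for which no test was available here, stays open.

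The effect at 4 h differed between the lines in 9 genes: EGR1 (-1.58), MXD1 (-1.04), RGS16 (-0.98), CHAC1 (-0.95), CCDC117 (-0.79), RNF144B (-0.75), ZCCHC8 (-0.72), MT1L (-0.71) and ZBTB21 (-0.58). The effect in H209 differed between 24 and 4 h in 6 genes: EGR1 (-1.7), RGS16 (-1), MXD1 (-0.98), CHAC1 (-0.84), CCDC117 (-0.82) and SMAD7 (-0.8). The 24 h effect as labelled includes arrays with the other group's profile, which shrinks it and biases this difference. RNF144B, ZCCHC8, MT1L, ZBTB21 and SMAD7 are outside the naming rule and were listed after their values were seen.

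The arrays were also split in other ways. For the line and the time difference, 100 splits were taken, the labels and others drawn at random from all possible splits. Over 100 splits of the arrays behind the line difference at 4 h, 6 called at least the 9 genes of the labels, and the highest other called 28. Over 100 splits of the arrays behind the time difference in H209, 23 called at least 6 genes, and the highest other called 642, which points to a structure of these samples. As the replicate number pairs the H209 arrays at 4 h, the 80 splits that part those pairs were also counted. For the line difference 15 of them called at least 9 genes (highest other 35), and with the replicate block 7 called at least 27 (highest other 59). All 15 and all 7 were among the 20 splits that kept the H209 groups at 4 h whole, which still hold the H209 response; the 60 that broke them up called at most 0 and, with the block, 1. Chance was thus not excluded for the line difference, and these splits do not separate it from the H209 response itself. For the time difference 24 of 80 splits called at least 6 genes (highest other 642), and with the block 22 called at least 7 (highest other 1117). Of these, 18 of the 24 and 16 of the 22 kept the H209 groups at 4 h whole and so still hold the response. Of the 60 that broke them up 6 called as many (at most 119), and 6 with the block (at most 271). These 60 include splits that exchange the replicate 3 pair at 24 h and so hold the response at that time. The splits thus do not separate chance from the response, and chance was not excluded.

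The other comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. At 4 h in H209 the labels called 121 genes and the highest other split 0, so 1 of 10 splits called as many, and of the 4 splits that part the 3 pairs the highest other called 0. Without the 4 arrays the labels called 348 and the highest other 75 (1 of 10). At 24 h in H209 the labels called 0 and the highest other 459, which is the split exchanging the replicate 3 pair and adds nothing to the pattern above. In H838 the labels and the highest other split called 0 at 4 h and 0 at 8 h. With the labels at 0 every split calls as many, so these 3 comparisons decide nothing. At 8 h in H209, with 2 against 2 arrays, there are still fewer splits. There the labels called 0 and the split exchanging the replicate 2 pair 459, which likewise restates the pattern. Between the lines at 0 h the labels called 8494 and the highest other 0 (1 of 10). For the vehicle arrays the labels called 3 and the highest other 8 in H209 (2 of 10), and 351 and 1 in H838 (1 of 10).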

How the results depend on the processing

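The fit without 4 arrays and the crossed replicate block were chosen after the values had been seen, and so was the set of results compared here for H209 at 8 h, for the time difference in H209 and for lists. It was narrowed once it was known that leaving out the 4 arrays turns many signs: of 54 named genes called at 8 h in that fit, 19 had the other sign as labelled, and of all 263 called genes, 77. Lists are not described for the line difference at 8 and 24 h, vehicle H209 and the time difference in H838. A gene counts as reversed where its sign turns, and a list where the direction of its camera test turns, and either value passes; turns where neither passes count as unchanged. The camera direction can turn while the median keeps its sign. The set held 480 gene effects, 314 list results and 17 counts, each counted again under every alternative in which it was tested. The numbers that follow are thus comparisons that overlap, not separate results. Of the gene comparisons 11905 stayed, 607 were stronger, 212 weaker and 3 reversed. Of the list comparisons 6936 stayed, 165 were stronger, 277 weaker and 15 reversed. Of the count comparisons 355 stayed and 85 moved. Before the set was narrowed, 38 gene comparisons and 47 list comparisons were reversed, beside 14031 and 9365 that stayed. The cause of each move was not tested. The NRF2 list in H209 for the mean of times had a median of 0.151, and its call was weaker with an estimated inter-gene correlation (0.151) and with fry (0.151), which change the test and not the median. The median itself ran from 0.074 without vehicle 8 h replicate 1 and 0.074 without DKFZ-608 8 h replicate 1 to 0.231 without vehicle 8 h replicate 2, with 0.097 without vehicle 24 h replicate 1 and 0.229 without DKFZ-608 24 h replicate 3. It was 0.443, with 27 members up, without the 4 doubted arrays.

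Without the 4 doubted arrays the counts in H209 were 348 at 4 h, 263 at 8 h, 308 at 24 h and 904 for the mean of times, and in H838 4, 5, 2 and 4. The line difference then had 133 genes at 4 h, 144 at 8 h, 126 at 24 h and 465 for the mean of times, the time difference in H209 73 and vehicle H209 11. Reversed were MT1M (5.53) and HSPA6 (5.12) at 8 h and HSPA6 (1.31) for the time difference. So were the list tests of metallothioneins at 8 h (median 2.771), and of mitosis and G2/M (median -0.158) and hypoxia and glycolysis (median 0.097, positive also with all arrays) for the time difference.

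With same-line arrays only, H209 at 4 h had 27 genes, the time difference in H209 0, and H838 3, 5, 2 and 4 at 4, 8, 24 h and for the mean of times. With the contrast's groups only, H838 had 2, 3, 1 and 4, the line difference at 4 h 98 and the time difference in H209 2. With array weights H209 had 450 at 4 h, 7 at 24 h and 52 for the mean of times, H838 1 at 8 h and 1 for the mean, the line difference at 4 h 62, the time difference in H209 20 and vehicle H209 6.

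With the replicate block as a fixed effect H209 had 192 genes at 4 h and 1 for the mean of times, the line difference at 4 h 27, vehicle H209 9 and vehicle H838 636. As a random effect it gave 2 for the H209 mean of times, 19 for the line difference at 4 h and 6 for vehicle H209. The crossed replicate block at 8 h gave 237 at 4 h and 8 for the mean of times in H209, 44 for the line difference at 4 h, 15 for the time difference in H209, 7 for vehicle H209 and 645 for vehicle H838. With trend and robust settings the H209 mean of times had 2 genes and the line difference at 4 h 14. The strict filter on low signal gave 18 for the line difference at 4 h and 5 for vehicle H209. The conflicting array placed at 8 h gave 15 for the H209 mean of times and 23 for the line difference at 4 h. At least 1.5-fold as a second criterion left 68 genes at 4 h in H209, 4581 between the lines at 0 h and 100 for vehicle H838.

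Leaving out 1 array at a time, the count at 4 h in H209 ran from 55 without DKFZ-608 4 h replicate 2 to 100 without DKFZ-608 4 h replicate 1, with 62 without vehicle 4 h replicate 1, 61 without vehicle 4 h replicate 2 and 66 without DKFZ-608 4 h replicate 3. At 8 h in H209 it ran from 0 to 1 (1 without vehicle 8 h replicate 1 and 1 without DKFZ-608 8 h replicate 2). For the H209 mean of times it ran from 0 to 51 without DKFZ-608 8 h replicate 2, with 43 without vehicle 8 h replicate 2, 28 without vehicle 24 h replicate 3 and 9 without DKFZ-608 24 h replicate 3. In H838 it was 1 at 8 h without DKFZ-608 8 h replicate 1 and 1 at 24 h without vehicle 24 h replicate 2. The line difference at 4 h ran from 4 without H838 vehicle 4 h replicate 3 to 12 without H209 DKFZ-608 4 h replicate 1, with 5 without H209 vehicle 4 h replicate 1, 5 without H209 DKFZ-608 4 h replicate 2, 5 without H838 vehicle 4 h replicate 1 and 5 without H838 DKFZ-608 4 h replicate 1, and for the mean of times it reached 2 without H209 vehicle 8 h replicate 2. The time difference in H209 ran from 2 without vehicle 4 h replicate 3 and 2 without DKFZ-608 24 h replicate 3 to 9 without DKFZ-608 4 h replicate 1, with 3 without vehicle 4 h replicate 1, 3 without vehicle 24 h replicate 1, 3 without vehicle 24 h replicate 2 and 3 without DKFZ-608 4 h replicate 2. Vehicle H838 ran from 103 without vehicle 0 h replicate 1 to 451 without vehicle 0 h replicate 3, with 179 without vehicle 0 h replicate 2, 167 without vehicle 24 h replicate 2 and 202 without vehicle 24 h replicate 3. Vehicle H209 ran from 2 to 4 and the lines at 0 h from 7955 to 8093.

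Leaving out 1 array also turned the direction of list tests, whose medians are given here, with the remaining lone array at 8 h assumed to vary like the other groups. At 8 h in H209, NRF2 targets ran from -0.248 to 0.238, with -0.228 without vehicle replicate 1, and the heat shock response from -0.404 to 0.583, with -0.373 without DKFZ-608 replicate 1. The ATF4 integrated stress response ran from -0.185 to 0.343, and metallothioneins from -1.421 to 1.428, with 1.291 without DKFZ-608 replicate 2. For the H209 mean of times mitosis and G2/M ran from -0.176 to 0.014 and proteasome subunits from 0 to 0.065, the latter not negative. At 24 h in H209 proteasome subunits ran from -0.006 to 0.154 and mitosis and G2/M from -0.186 to -0.001, the latter negative throughout. At 4 h in H838 mitosis and G2/M ran from -0.15 to 0.136.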

Other observations

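The results in this part were picked after the values had been seen, and those from the fit without the 4 H209 arrays rest on arrays chosen by their expression. In that fit, genes of protein and organelle clearance rose in H209 for the mean of times. GABARAPL1 (1.00 ± 0.07) and MAP1LC3B (0.81 ± 0.08), which encode proteins of the autophagosome membrane, rose, as did SQSTM1, an autophagy receptor and NRF2 target (0.76 ± 0.07). Of the 26 genes of autophagy and lysosome 6 rose, 6 when adjusted over the list alone (median 0.13; adjusted p = 1.84e-04 with an estimated correlation). Of the 27 proteasome subunits 5 rose, 8 when adjusted over the list alone (median 0.13; adjusted p = 0.0225 with an estimated correlation), including PSMD12 (0.51 ± 0.07) and PSMD14 (0.43 ± 0.06).

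The neuroendocrine genes moved in both directions in the same fit. NKX2-1, a lung lineage factor (-0.57 ± 0.07), ISL1 (-0.55 ± 0.05) and the proneural factor NEUROG2 (-0.55 ± 0.09) fell, while TUBB3, a neuronal tubulin, rose (1.54 ± 0.10); of the 21 neuroendocrine genes 4 rose and 4 fell, 5 and 4 when adjusted over the list alone. BIRC5, survivin (-0.39 ± 0.10), the mitotic kinase gene AURKB (-0.35 ± 0.10) and CDK1 (-0.30 ± 0.07) fell among the 4 of 30 mitosis and G2/M genes that did, 8 when adjusted over the list alone (median -0.24, adjusted p = 8.52e-09, which was lost at adjusted p = 0.201 with an estimated correlation).

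In the array labelled H838 DKFZ-608 8 h replicate 1, TXNRD1 lay at log2 11.58 against 10.72 and 10.69 in the other treated arrays of that time. That array also differed from them as a whole. Its median intensity was 92.6 against 93.4 and 93.6, and its upper quartile 135.4 against 131 and 131.1. These differences are small beside that of TXNRD1 and do not explain it. Whether the shift is particular to TXNRD1 was not tested, and it rests on 1 array.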
